A study of Mus musculus with 8 samples.

How the data were processed

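Mouse embryonic stem (ES) cells of 2 genotypes were profiled on Affymetrix GeneChip mouse arrays of the 430 2.0 type, with 8 arrays in 4 groups of 2. Per the labels, the groups were Rbp2f/f and Rbp2-/- cells grown with leukemia inhibitory factor (LIF), the cytokine that keeps mouse ES cells undifferentiated, and the same genotypes after 6 days in medium lacking it. The labels call the 2 samples of each group biological replicates, without saying which cultures or clones they came from, so the p-values measure the spread between these samples only, part of which may be technical. RBP2 was read as retinoblastoma-binding protein 2, a histone H3 lysine 4 demethylase whose gene is now named Kdm5a, and not as retinol-binding protein 2. Per the labels' protocols, RNA was purified on columns with DNase digestion and biotin-labelled cRNA was made from 6 ug of total RNA.

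The deposited values are intensities on a linear scale, already summarised per probe set by the authors, from 0.1 to 11476.5 with 39 values of 0. The summarisation software, background correction and scaling target are not given in the sources used here, so the scale of the intensities stays unknown apart from being linear and not centred. The median intensity per array was 22.3 and 19.0 in Rbp2f/f with LIF and 19.0 and 15.7 in Rbp2-/- with LIF. Without LIF it was 20.9 and 21.8 in Rbp2f/f, and 22.3 and 24.6 in Rbp2-/-. Replicate 2 of Rbp2-/- with LIF had a 2% trimmed mean of 77.5, which is 65.5% of the mean of the other arrays, so the arrays had not all been brought to the same level. The number of arrays limits the precision, and no counting error applies.

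Of 45101 probe sets, 34958 had 1 gene symbol in the platform's annotation table, 932 had several and 9211 had none there, including 64 manufacturer controls. Gene identifiers of 34754 probe sets were found in a reference gene table of assembly GRCm38.p6, used only for names, and 0 symbols needed updating. Probe sets with several genes or none were named after no gene. Each gene was represented by its probe set with the highest mean over all 8 arrays, which gave 18193 genes. Genes with a mean at or above the 40th percentile were tested, leaving 10916.

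Intensities were transformed as log2(value + 16). A fold on this scale understates the change of dim genes. The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit on 4 group means over all 8 arrays and eBayes with a mean-variance trend, with 4 residual and 11.2 prior degrees of freedom. Contrasts were the genotype effect with LIF, the genotype effect without LIF, LIF withdrawal in each genotype, and the difference of these withdrawal effects (the interaction). P-values were two-sided and adjusted by Benjamini-Hochberg over the 10916 genes of each contrast, and a gene was called at an adjusted p under 0.05. Errors given with log2 values are standard errors from this fit, and errors given with intensities are standard deviations of 2 arrays.

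The design, the alternatives, the rule for naming genes and 28 gene lists were fixed before the data were examined. Named genes were Kdm5a, up to 10 with the largest increase and 10 with the largest decrease per contrast among called genes whose arrays did not overlap between the groups, and, in each list, the 4 members with the smallest p, or every member of a list with under 8. For the interaction, which called none, the 5 genes with the smallest p were named. Genes known only by a clone, accession or predicted name were counted and not named. Of the 624 list members, 574 were measured here. Lists with 3 or more tested members, 26 of the 28, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with the correlation estimated from the data, and fry was run beside it. With 2 arrays per group the repeat of camera has little power, so a list that misses it is not shown to be unchanged. The 2-cell-stage list had 0 tested members and the Y-linked list 2, Eif2s3y and Uty, which are given as single genes.

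Because 1 array was dim, the median difference of all genes was far from 0 in several contrasts. It was -0.28 for the genotype effect with LIF, 0.02 without LIF, 0.07 for withdrawal in Rbp2f/f, 0.39 for withdrawal in Rbp2-/- and 0.31 for the interaction, and lay between -0.02 and 0.01 after quantile normalization. Changes in the contrasts shifted by over 0.1 are therefore given relative to the all-gene median, and results after quantile normalization stand beside those on the values as deposited. The limma p-values of single genes test the changes before that median was subtracted. Other alternatives were median centring, other filters and pseudocounts, other variance models and array weights, other summaries of several probe sets, a stricter threshold, the replicate number as a block, and leaving out each array.

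The pipeline was tested on simulated data for the genotype effect with LIF, with 200 changed genes among 10916 in 10 simulations. With level arrays it recovered 42.2% of genes changed 2-fold and 99.2% of those changed 4-fold, and 7.0% of its calls were false. With 1 array dimmed by -0.40 in log2, recovery was 34.4% and 99.0% with 10.3% false calls, and the estimates at 4-fold were biased by -0.18. Quantile normalization of these dimmed arrays gave 40.3%, 98.3% and 7.1%. A list made only of genes raised 2-fold was called in 10 of 10 simulations, and 0% of the lists without changed members were. The dimming was equal in log2 for all genes, so a dimming that depends on intensity was not simulated. The simulated genes varied independently of each other. The simulation therefore cannot tell how often lists of genes that vary together are called falsely.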

Results

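Transcript levels were measured in mouse ES cells carrying intact (Rbp2f/f) or deleted (Rbp2-/-) copies of the gene for RBP2, with LIF and after 6 days without it. Each of the 4 groups had 2 arrays, so every group mean has n = 2. The 2% trimmed mean intensity was 115.9 and 116.8 in Rbp2f/f with LIF, 117.9 and 121.3 in Rbp2f/f without LIF, and 117.2 and 128.4 in Rbp2-/- without LIF. In Rbp2-/- with LIF it was 110.5 in replicate 1 and 77.5 in replicate 2. Over the tested genes, replicate 2 of Rbp2-/- with LIF lay at a median of -0.46 in log2 from the mean of the arrays. Replicate arrays correlated at 0.961 to 0.982 across genes, which are not independent replicates. That dim array correlated at 0.901 to 0.925 with the arrays without LIF, against 0.865 to 0.893 for replicate 1 of its group. Replicate 2 of Rbp2-/- without LIF correlated at 0.979 with replicate 1 of Rbp2f/f without LIF, against 0.972 with the other array of its own group. The ratio of 3' to 5' signal for Gapdh, a control for RNA and labelling quality, was 1.11 in replicate 1 of Rbp2f/f with LIF and 0.78 to 0.85 in the others. Signal from 18S ribosomal RNA was 383.8 and 357.2 in Rbp2f/f with LIF, 129.1 and 45.6 in Rbp2-/- with LIF, 191.4 and 92.1 in Rbp2f/f without LIF, and 73.2 and 123.0 in Rbp2-/- without LIF.

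Kdm5a, the targeted gene, was lower in Rbp2-/- than in Rbp2f/f cells on every array. With LIF its brightest probe set read 128.2 and 167.2 in Rbp2f/f against 31.2 and 30.6 in Rbp2-/-, so that 20.9% of the signal remained. The log2 difference was -1.79 ± 0.26 (limma adjusted p = 0.022), or -1.51 relative to the all-gene median. Without LIF the values were 225.7 and 246.6 against 100 and 80.2, a remaining share of 38.2%. This difference, -1.25 ± 0.26, missed the threshold after adjustment (adjusted p = 0.088). Of the other 5 Kdm5a probe sets, a pair of brighter ones left 17.5% and 20.4% with LIF, and 42.3% and 51.1% without LIF. The remaining 3 were dim, at or under 23.0 on every array. Of these 1 was lower in each Rbp2-/- array than in the Rbp2f/f arrays of the same medium, leaving 77.3% with LIF and 66.4% without, and the other pair was not. Kdm5a signal rose by 1.17 ± 0.26 on withdrawal in Rbp2-/- cells (adjusted p = 0.0052), or 0.79 relative to the all-gene median, and the value in Rbp2f/f was 0.63 ± 0.26 (adjusted p = 0.096). These withdrawal effects were not shown to differ (interaction 0.54 ± 0.36, adjusted p = 0.54, or 0.23 relative to the all-gene median). Where the probes lie relative to the deleted part of the gene was not analysed here, so the signal checks the labels without measuring intact transcript. The call with LIF was lost after quantile normalization (adjusted p = 0.078) and without replicate 2 of Rbp2f/f with LIF (0.23) or replicate 2 of Rbp2-/- with LIF (0.14), within a range of 0.00019 to 0.33 over all alternatives. Without LIF that range was 0.0077 to 1.

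**Figure D1:**
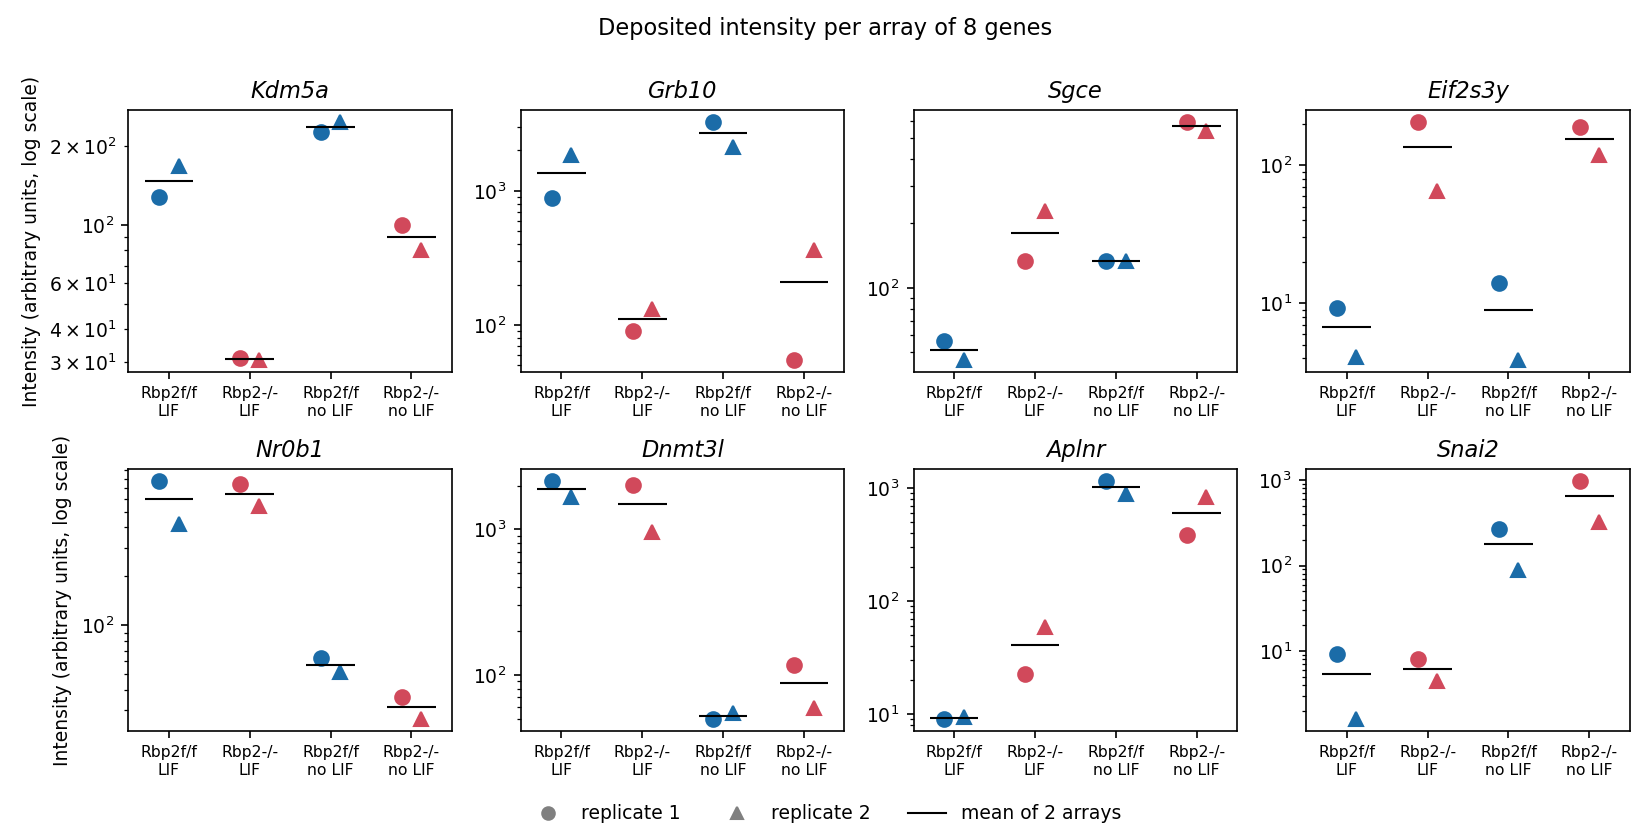
Deposited intensity (arbitrary units, log scale) of 8 genes on each of the 8 arrays, with circles for replicate 1, triangles for replicate 2 and a line at the mean of 2 arrays. Kdm5a reads 30.6 to 31.2 in Rbp2-/- with LIF and 80.2 to 100 without LIF, below each Rbp2f/f array, and Eif2s3y reads 64.8 or more in the Rbp2-/- arrays and at most 14.0 in the Rbp2f/f arrays.

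The comparison of genotypes in medium with LIF asks which transcripts differ between Rbp2-/- and Rbp2f/f cells before withdrawal. Grb10 is an imprinted gene encoding an adaptor that restrains insulin and growth factor signalling. It read 1360 ± 676 in Rbp2f/f and 110 ± 29.1 in Rbp2-/- (SD, n = 2). Among the genes named for this comparison, its difference was the largest on the log2 scale used, which understates the change of dim genes. Its log2 difference was -3.10 ± 0.55 relative to the all-gene median of -0.28, and the changes that follow are relative to the same median. Slc27a2, a fatty acid transporter and acyl-CoA synthetase, fell by 2.33 ± 0.35. Eif2s3y, a Y-linked translation initiation factor gene, was higher by 2.85 ± 0.40, from 6.70 ± 3.68 to 135 ± 99.1. It was dim in Rbp2f/f, so its rank below Grb10 may not hold on another scale. Sgce, an imprinted gene for a sarcoglycan, was higher by 1.79 ± 0.28.

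In all, 25 of 10916 genes passed with LIF, 7 higher and 18 lower in Rbp2-/-. The others that were higher were Gbp2 (an interferon-induced GTPase, 2.57 ± 0.39), Bmp2 (a bone morphogenetic protein ligand, 2.54 ± 0.36), Col5a1 (a fibrillar collagen, 1.80 ± 0.28), Hmga2 (a chromatin architectural protein, 1.74 ± 0.26) and Vim (the intermediate filament vimentin, 1.56 ± 0.21). In Rbp2f/f these genes also read higher without LIF, at 668, 433, 648, 3700 and 6610 against 60, 15.5, 108, 329 and 1980 with it. Hnrnph3 (an RNA-binding protein, -1.72 ± 0.32), Cd99 (a surface glycoprotein, -1.70 ± 0.32) and Smarca1 (a chromatin remodelling ATPase, -1.61 ± 0.33) were lower, as were Csn3 (kappa-casein, -1.61 ± 0.28) and Pim2 (a serine/threonine kinase, -1.59 ± 0.36). Dcaf12l1 fell by 1.5 ± 0.32, and Esrp1, an epithelial splicing regulator, fell by 1.49 ± 0.33. All of these had a limma adjusted p of 0.047 or less, tested before the all-gene median was subtracted. After quantile normalization limma called 0 genes, with 1421 at an unadjusted p under 0.05 against 1920 as deposited and a smallest adjusted p of 0.078, and median centring also gave 0. With the replicate number as a block it called 140. The count was 0 without replicate 2 of Rbp2-/- with LIF and 2425 without replicate 1 of that group, 2 without replicate 2 of Rbp2f/f with LIF, and 38 or 40 without either Rbp2f/f array lacking LIF.

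Among the 26 lists tested with LIF, camera called 8 as higher and 1 as lower in Rbp2-/-, by comparison with all other genes. Epiblast-stage genes, which mark cells leaving the naive state, had a median of -0.73 over 13 members (adjusted p = 0.0043; adjusted p = 0.63 with an estimated correlation). None of the 13 passed over all genes, and 7 were lower when adjusted over the list alone. Otx2, a homeobox factor of epiblast and forebrain, was at -1.64 ± 0.48, Pou3f1, a neural and epiblast POU factor, at -1.80 ± 0.51 and the DNA methyltransferase Dnmt3b at -0.94 ± 0.30. Mesoderm derivatives had a median of 0.35 over 17 members (adjusted p = 2.1e-05; adjusted p = 0.51 with an estimated correlation), with 0 passing over all genes and 1 higher adjusted over the list alone. Their smallest p belonged to Bmp4, a ventral mesoderm ligand, at 1.52 ± 0.28. Feeder fibroblast markers, fixed as a sign of feeder cells in the culture, stood at 0.48 over 17 members, with Col5a1 passing over all genes and 3 higher adjusted over the list alone (adjusted p = 1.9e-05; adjusted p = 0.49 with an estimated correlation). Imprinted genes stood at 0.43 over 22 members (adjusted p = 4.6e-05; adjusted p = 0.49 with an estimated correlation), with Sgce higher and Grb10 lower over all genes, and 6 higher and 3 lower adjusted over the list alone.

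Interferon-stimulated genes (0.41), smooth muscle and SRF target genes (0.29), primitive streak genes (0.52), extraembryonic endoderm (0.29) and trophoblast genes (0.24) were also called higher with LIF. Their adjusted p were 0.00075, 0.0014, 0.0043, 0.0052 and 0.0052, and with an estimated correlation adjusted p = 0.49, 0.78, 0.78, 0.49 and 0.58. No member of these 5 lists passed over all genes, and adjusted over the list alone Krt19 in the trophoblast list and Cited1 in the endoderm list were higher and Lamb1, also in the endoderm list, was lower. Before the all-gene median was subtracted, the trophoblast median was -0.04 and its mean 0.04. The endoderm, SRF, interferon and streak medians were then 0.01, 0.02, 0.13 and 0.24. Those of mesoderm derivatives, feeder markers and imprinted genes were 0.07, 0.20 and 0.15. The streak, endoderm and trophoblast calls were lost after quantile normalization, which left 6 lists, 5 higher and 1 lower. Without replicate 2 of Rbp2f/f with LIF 3 lists were called, all higher, and without replicate 2 of Rbp2-/- with LIF 4 were, 1 higher and 3 lower. In the latter case the SRF median turned to -0.10 (adjusted p = 0.81), the streak, endoderm and interferon medians were 0.19, 0.07 and 0.21, and of the higher lists the interferon list alone stayed called. It was also the only 1 of the 9 lists to stay called whichever of the 8 arrays was left out. Over these 8 settings the medians ranged from -1.06 to -0.49 for epiblast-stage genes, 0.12 to 0.59 for mesoderm derivatives, 0.28 to 0.66 for feeder markers, 0.28 to 0.56 for imprinted genes, 0.21 to 0.52 for interferon genes, -0.10 to 0.71 for SRF targets, 0.19 to 0.86 for streak genes, 0.07 to 0.53 for endoderm and 0.002 to 0.58 for trophoblast genes. Signal from 18S RNA was also lower in these Rbp2-/- arrays. Pluripotency factors did not pass (median -0.02 with the test directed upward, 28 members, adjusted p = 0.82), nor did LIF and STAT3 responsive genes (0.18, 20 members, adjusted p = 0.22). H3K4 methylation enzymes other than Kdm5a did not pass either (-0.18, 18 members, adjusted p = 0.11). In the epithelial list (-0.17, 17 members, adjusted p = 0.13) Esrp1 alone was lower over all genes, with 4 lower adjusted over the list alone, and in the neuroectoderm list Olig2, a bHLH factor of neural progenitors, was at -1.48 ± 0.34.

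In medium without LIF the genotypes were compared to ask which transcripts differ among differentiating cells. Grb10 fell by 4.01 ± 0.55, from 2690 ± 798 to 208 ± 216 (SD, n = 2), Sgce rose by 1.97 ± 0.28 and Eif2s3y rose by 2.77 ± 0.40. Limma called these 3 genes (adjusted p = 0.018 each), and all of them had also been called with LIF in the same direction. Eif2s3y is Y-linked and the others are imprinted. For them a separate history of the cell lines could not be told apart from an effect of losing RBP2. The 2 genotype comparisons share no array, and their fold changes correlated at 0.15 across genes. After quantile normalization 0 genes were called, with 1550 at an unadjusted p under 0.05 against 1091 as deposited, and median centring also gave 0. With the replicate number as a block 149 were called. Leaving out replicate 1 of Rbp2-/- without LIF gave 0, leaving out its replicate 2 gave 125 and leaving out replicate 1 of Rbp2f/f without LIF gave 61, while 1 was called without either Rbp2-/- array with LIF or without replicate 2 of Rbp2f/f lacking LIF.

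Epithelial genes were called lower in Rbp2-/- cells without LIF, with a median of -1.07 relative to all genes and 17 of 17 members negative (camera adjusted p = 6.1e-14; adjusted p = 0.37 with an estimated correlation). None passed over all genes, and 10 were lower adjusted over the list alone. The claudins Cldn3 and Cldn4, tight junction proteins, were at -1.59 ± 0.35 and -1.88 ± 0.45, and Cdh1, which encodes E-cadherin, was at -1.45 ± 0.38. Targets of p53 had a median of -0.51 (adjusted p = 3.4e-08; adjusted p = 0.37 with an estimated correlation), with 0 of 18 passing and 5 lower adjusted over the list alone. They included Perp, a desmosome-associated membrane protein, at -1.31 ± 0.33 and the apoptosis gene Pmaip1 at -1.08 ± 0.33. Smooth muscle and SRF target genes stood at -0.62 (adjusted p = 1.4e-07; adjusted p = 0.41 with an estimated correlation), with 0 of 17 passing and 1, the matricellular gene Ccn2 at -1.72 ± 0.48, lower adjusted over the list alone. Metallothionein and zinc response genes stood at -1.06 (adjusted p = 0.00016; adjusted p = 0.37 with an estimated correlation). None of their 5 members passed and 3 were lower adjusted over the list alone, namely Mt1 (-1.20 ± 0.27), Mt2 (-1.03 ± 0.26) and the zinc exporter Slc30a1 (-1.35 ± 0.33). After quantile normalization the metallothionein and zinc response list, then of 6 members, stood at -0.62 (adjusted p = 0.010).

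Glycolysis and hypoxia genes were called higher without LIF, at 0.56 with 19 of 19 members positive (adjusted p = 2.5e-08; adjusted p = 0.41 with an estimated correlation). None passed over all genes, and 3 were higher adjusted over the list alone. Egln3, an oxygen-sensing prolyl hydroxylase, was at 1.57 ± 0.37 and the angiogenic factor Vegfa at 1.09 ± 0.33. Mitosis genes (0.44, 19 of 19 positive) and E2F target and DNA replication genes (0.32, 24 of 24 positive) had adjusted p = 9.4e-07 and 2.3e-06, and adjusted p = 0.41 for both with an estimated correlation. No member of either passed over all genes or adjusted over the list alone. The spindle checkpoint gene Mad2l1 was at 0.93 ± 0.29 and Ccna2, which encodes cyclin A2, at 0.74 ± 0.24. Imprinted genes (0.54), cholesterol synthesis (0.41), mesoderm derivatives (0.28) and oxidative phosphorylation (0.12) were also called higher, with adjusted p = 0.00035, 0.00035, 0.0011 and 0.0066, and adjusted p = 0.37, 0.42, 0.41 and 0.64 with an estimated correlation. Over all genes only Sgce and Grb10, both imprinted, passed among these lists. Adjusted over the list alone, 9 imprinted genes were higher and 3 lower, 6 mesoderm derivatives were higher and 1 lower, and 0 members passed in the other pair. Msx2, a mesodermal homeobox gene, was at 1.49 ± 0.33 and the heart and lateral mesoderm factor Hand1 at 1.78 ± 0.52.

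Pluripotency factors (-0.46), LIF and STAT3 responsive genes (-0.39), neuroectoderm (-0.60), CDK inhibitors and pocket proteins (-0.70), interferon-stimulated genes (-0.33), extraembryonic endoderm (-0.36) and primitive streak genes (-0.52) were called lower in Rbp2-/- without LIF. Their adjusted p were 0.00015, 0.00038, 0.00035, 0.012, 0.021, 0.025 and 0.025, and with an estimated correlation adjusted p = 0.42, 0.41, 0.37, 0.37, 0.41, 0.41 and 0.55. No member of these lists passed over all genes. Adjusted over the list alone, 5 CDK inhibitors and pocket proteins, 3 neuroectoderm genes and 2 LIF and STAT3 responsive genes were lower, endoderm gave 4 lower and 1 higher, and the pluripotency, interferon and streak lists gave 0. The CDK inhibitor list included Rb1, the retinoblastoma gene, at -0.66 ± 0.26 and Cdkn1c at -2.60 ± 0.91, which read 19.1 and 925.3 in the Rbp2-/- replicates against 1019.5 and 1156.1 in Rbp2f/f. Tfcp2l1, a naive pluripotency factor, was at -1.06 ± 0.29. The CDK inhibitor and streak calls were lost after quantile normalization (adjusted p = 0.073 and 0.086). Without replicate 1 of Rbp2-/- lacking LIF the epithelial, SRF and glycolysis medians were -0.70, -0.37 and 0.33, and without replicate 2 they were -1.48, -1.04 and 0.78, all still called. With any 1 of the 8 arrays left out, medians ranged from -1.06 to -0.495 for metallothionein genes, 0.17 to 0.48 for E2F targets, 0.27 to 0.78 for imprinted genes, 0.06 to 0.17 for oxidative phosphorylation, 0.32 to 0.43 for mesoderm derivatives and 0.30 to 0.61 for mitosis genes. They ranged from -0.64 to -0.25 for LIF and STAT3 genes, -0.835 to -0.385 for neuroectoderm, -0.97 to -0.44 for CDK inhibitors, -0.353 to -0.215 for interferon genes and -0.54 to -0.10 for endoderm. Of the 18 lists 12 stayed called whichever array was left out, and the imprinted, oxidative phosphorylation, CDK inhibitor, interferon, endoderm and streak lists did not. The streak list moved with a single array: its median differed by 1.61 between the 2 Rbp2-/- replicates without LIF, and it turned to 0.443 without replicate 1 and was -1.173 without replicate 2. Without either Rbp2-/- array with LIF, which this comparison does not hold, the call was lost (adjusted p = 0.067 and 0.090). Feeder fibroblast markers did not pass in this comparison (0.14, 17 members, adjusted p = 0.38), nor did H3K4 methylation enzymes (-0.03, 18 members, adjusted p = 0.81).

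**Figure D2:**
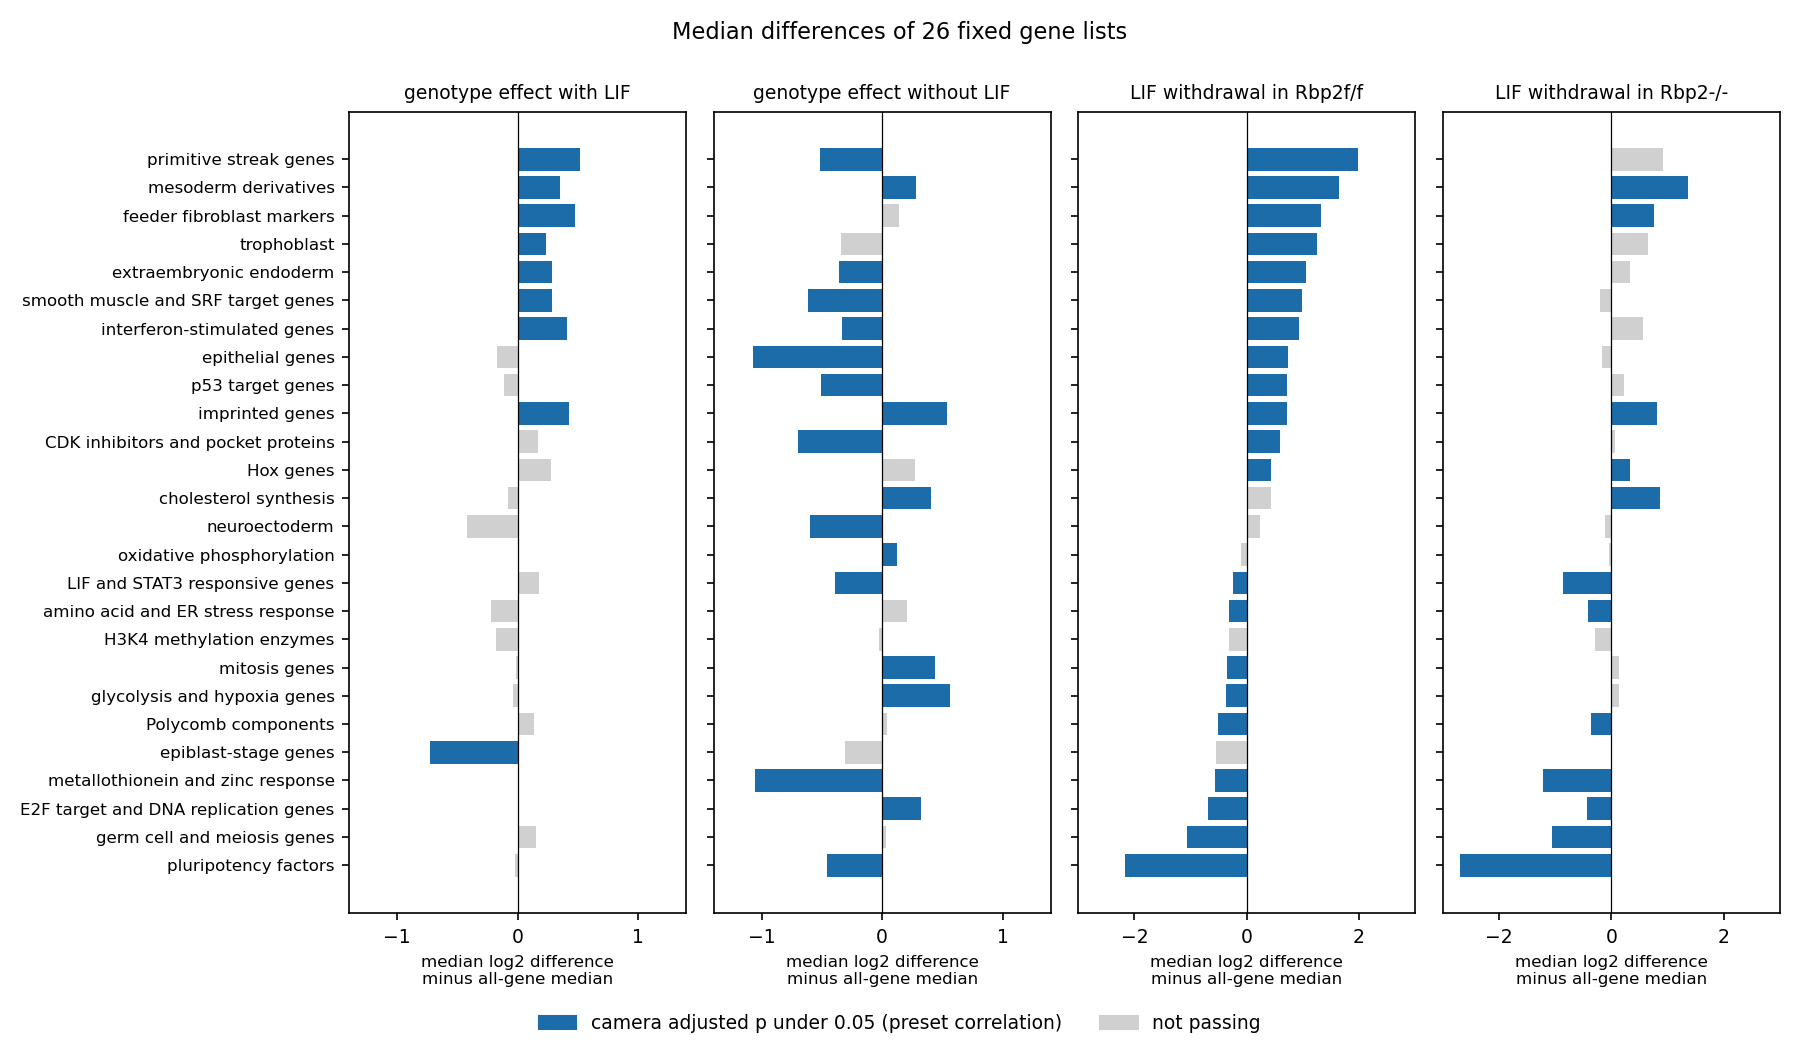
Median log2 difference of 26 fixed gene lists minus the median of all 10916 genes, for both genotype comparisons (Rbp2-/- minus Rbp2f/f) and both withdrawal comparisons (without minus with LIF), with blue bars where camera at the preset correlation gave an adjusted p under 0.05. Pluripotency factors stand at -2.16 and -2.70 in the withdrawal panels and epithelial genes at -1.07 in the genotype panel without LIF; no bar passes with an estimated correlation.

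Withdrawal of LIF from Rbp2f/f cells asks how the genotype with intact RBP2 responds to differentiation. Aplnr, the apelin receptor of early mesoderm, rose by 5.35 ± 0.37 in log2, from 9.30 ± 0.283 to 1020 ± 185 (SD, n = 2), and Cdh11, a mesenchymal cadherin, rose by 4.15 ± 0.27. Dnmt3l, a cofactor of de novo DNA methylation, fell by 4.81 ± 0.36, from 1910 ± 328 to 52.0 ± 3.32, and the pluripotency-associated gene Dppa2 fell by 3.91 ± 0.29. Lhx1 (3.93 ± 0.63) and Mixl1 (3.65 ± 0.60), homeobox genes of the primitive streak, rose as well. So did Bmp2 (3.92 ± 0.36), the retinoic acid-degrading enzyme gene Cyp26a1 (3.75 ± 0.55), the zinc finger gene Zfp703 (3.58 ± 0.48), the serine protease gene Tmprss2 (3.51 ± 0.38), Hmga2 (3.45 ± 0.26) and the angiomotin gene Amot (3.45 ± 0.30). The non-coding transcripts Platr10 (-3.90 ± 0.26) and Lncenc1 (-3.37 ± 0.37) fell. Slc27a2 (-3.67 ± 0.35), Fbxo15 (-3.53 ± 0.40), Olig2 (-3.48 ± 0.34), L1td1 (-3.42 ± 0.42), Tcf15 (-3.41 ± 0.39) and Eras, the ES cell Ras gene (-3.37 ± 0.35), fell too. Each of these genes had a limma adjusted p of 0.00073 or less.

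In total 2188 genes changed in Rbp2f/f, 1446 higher and 742 lower without LIF, so that 66.1% of calls were higher. After quantile normalization there were 2921, of which 1505 were higher and 1416 lower (51.5% higher), and 2016 genes were called in the same direction both ways. Leaving out an array of the comparison gave 856 to 1297 genes (856 without replicate 2 and 1161 without replicate 1 of the arrays without LIF, 1138 without replicate 1 and 1297 without replicate 2 of those with LIF). Leaving out replicate 1 or 2 of Rbp2-/- with LIF, which this comparison does not hold, gave 3287 and 3304.

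Of the 28 pluripotency factors, 25 fell in Rbp2f/f, 1 rose and 2 did not pass, with a median of -2.16 relative to all genes (camera adjusted p = 2.2e-24; adjusted p = 0.34 with an estimated correlation). The counts were the same adjusted over the list alone. Beside Dppa2, the nuclear receptor gene Nr0b1 (-3.0 ± 0.31), the TGF-beta family ligand gene Gdf3 (-2.87 ± 0.30) and Dppa5a (-1.90 ± 0.18) fell. The member that rose was Tbx3, at 0.86 (adjusted p = 0.049), a gene named after its value was seen, whose call was lost after quantile normalization. Of 12 primitive streak genes 9 rose (median 1.99, adjusted p = 0.00012; adjusted p = 0.39 with an estimated correlation), among them Evx1 at 2.48 ± 0.34 and Foxa2 at 1.68 ± 0.29. Adjusted over the list alone 9 were higher and 1 lower. Of 17 mesoderm derivatives 12 rose and 1 fell, 13 and 1 adjusted over the list alone (median 1.65, adjusted p = 1.2e-06; adjusted p = 0.34 with an estimated correlation). Msx1 (2.71 ± 0.39), Bmp4 (2.37 ± 0.28) and Twist1 (1.96 ± 0.26) were among them. Extraembryonic endoderm genes gave 10 higher, 1 lower and 7 not passing, with the same counts adjusted over the list alone (median 1.05, adjusted p = 6.8e-05; adjusted p = 0.34 with an estimated correlation). Gata6, an endoderm transcription factor, rose by 2.65 ± 0.33 and the X-linked homeobox gene Rhox5 fell by 2.65 ± 0.42. Trophoblast genes gave 8 higher and 1 lower of 14, 9 and 1 adjusted over the list alone (median 1.26, adjusted p = 0.0015; adjusted p = 0.35 with an estimated correlation), with Cdx2 at 1.95 ± 0.30 and Krt19 at 2.66 ± 0.26.

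Feeder fibroblast markers rose with these lists in Rbp2f/f, 12 of 17 over all genes and 12 adjusted over the list alone (median 1.32, adjusted p = 6.8e-05; adjusted p = 0.34 with an estimated correlation). They include collagens that mesoderm also expresses, such as Col3a1 (2.33 ± 0.35) and Col5a1 (2.42 ± 0.28), and Pdgfrb rose by 2.18 ± 0.27. Smooth muscle and SRF target genes gave 9 of 17 higher, 12 adjusted over the list alone, with Tpm1 at 1.89 ± 0.20. Epithelial genes gave 7 of 17 higher, and 8 higher and 1 lower adjusted over the list alone, with the keratin Krt18 at 1.59 ± 0.26 and Dsp, the desmosomal protein desmoplakin, at 2.32 ± 0.41. Interferon-stimulated genes gave 6 of 12 higher, 7 adjusted over the list alone, with Usp18 at 2.49 ± 0.26 and Psmb8, an immunoproteasome subunit, at 2.44 ± 0.27. Targets of p53 gave 9 of 18 higher, 10 adjusted over the list alone, with the cell cycle inhibitor Cdkn1a at 2.03 ± 0.34. Imprinted genes gave 9 higher and 2 lower of 22, 10 and 2 adjusted over the list alone, with the growth factor Igf2 at 2.64 ± 0.31. Camera called these 5 lists higher, with medians of 0.98, 0.73, 0.94, 0.71 and 0.71, adjusted p = 0.00012, 0.023, 0.00054, 0.00039 and 0.0044, and with an estimated correlation adjusted p = 0.45, 0.58, 0.34, 0.38 and 0.34. Hox genes (3 of 7 higher, also adjusted over the list alone) and CDK inhibitors and pocket proteins (2 of 8 higher, 3 adjusted over the list alone) had adjusted p = 0.023 each, and adjusted p = 0.38 and 0.35 with an estimated correlation.

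Replication and amino acid genes went the other way in Rbp2f/f. Of 24 E2F target and DNA replication genes 11 fell and 0 rose, 13 and 0 adjusted over the list alone (median -0.69, adjusted p = 6.8e-07; adjusted p = 0.39 with an estimated correlation). The genes for the licensing factor Cdt1 (-1.5 ± 0.22) and the helicase subunit Mcm5 (-1.14 ± 0.22) fell. Of 21 amino acid and ER stress response genes 7 fell and 2 rose, 8 and 2 adjusted over the list alone (median -0.31, adjusted p = 0.0028; adjusted p = 0.47 with an estimated correlation), with the amino acid transporter Slc7a5 at -2.19 ± 0.32. LIF and STAT3 responsive genes gave 7 of 20 lower, the same adjusted over the list alone, with Klf4, a transcription factor induced by LIF, at -2.05 ± 0.26. Polycomb components gave 6 lower and 1 higher of 18, 7 and 2 adjusted over the list alone, with Cbx7 at -2.45 ± 0.28 and Jarid2 at -1.69 ± 0.30. Camera called this pair lower with adjusted p = 0.024 and 0.010, and adjusted p = 0.55 and 0.58 with an estimated correlation. Mitosis (1 of 19 lower), metallothionein (2 of 5 lower), germ cell (2 of 5 lower) and glycolysis genes (2 lower and 2 higher of 19) were also called lower, with adjusted p = 0.010, 0.049, 0.0053 and 0.042, and adjusted p = 0.60, 0.45, 0.39 and 0.65 with an estimated correlation. Adjusted over the list alone these gave 1, 2 and 3 lower, and 3 lower with 2 higher. The metallothionein and zinc response median was -0.56, and -0.90 after quantile normalization. Epiblast-stage genes (5 lower and 2 higher of 13), neuroectoderm (2 lower and 3 higher of 8, with a median of 0.24, and a mean of -0.07 before the all-gene median was subtracted), cholesterol synthesis (2 higher of 16), H3K4 methylation enzymes (2 lower of 18) and oxidative phosphorylation (0 of 48) did not pass as lists. Camera called 21 lists in all. After quantile normalization it called 18, without the LIF and STAT3, Hox, glycolysis and CDK inhibitor lists (adjusted p = 0.080, 0.067, 0.15 and 0.050) and with H3K4 methylation enzymes as lower (adjusted p = 0.028). Of the 21 lists 13 stayed called whichever array was left out. The LIF and STAT3 (-0.51 to -0.14), epithelial (0.42 to 1.01), CDK inhibitor (0.42 to 0.80), mitosis (-0.615 to -0.095), metallothionein (-1.05 to -0.45), Hox (0.36 to 0.71), amino acid (-0.53 to -0.28) and glycolysis lists (-0.50 to -0.18) did not. Among those that did, interferon genes ranged from 0.80 to 1.44 and imprinted genes from 0.56 to 1.13.

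Withdrawal of LIF from Rbp2-/- cells asks the same of cells lacking RBP2. The all-gene median was 0.39 in this comparison, which holds the dim array, and changes are given relative to it. Snai2, a repressor of epithelial genes in mesenchymal transitions, rose by 4.32 ± 0.47, from 6.20 ± 2.55 with LIF to 647 ± 460 without (SD, n = 2), and Cdh11 rose by 3.91 ± 0.27. Dnmt3l fell by 4.21 ± 0.36 and Dppa2 fell by 4.19 ± 0.29. Other increases were in Hbb-bh1 (an embryonic globin, 3.91 ± 0.91), Tdo2 (tryptophan dioxygenase, 3.67 ± 0.59), Car4 (a carbonic anhydrase, 3.37 ± 0.46), Hand1 (3.25 ± 0.52), Prdm6 (3.23 ± 0.28), Smad6 (an inhibitor of BMP signalling, 3.21 ± 0.31), Dkk1 (a Wnt antagonist, 3.18 ± 0.29) and Cxcr4 (a chemokine receptor, 3.17 ± 0.27). Nr0b1 (-4.16 ± 0.31), Fbxo15 (-4.16 ± 0.40), Tex19.1 (-3.76 ± 0.62), Morc1 (-3.72 ± 0.38) and Esrrb, a nuclear receptor of naive ES cells (-3.62 ± 0.29), fell as well. So did L1td1 (-3.52 ± 0.42), Rbmxl2 (-3.42 ± 0.29) and Eras (-3.40 ± 0.35). Each of these genes had a limma adjusted p of 0.0042 or less, and 0.037 or less after quantile normalization.

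In Rbp2-/- cells 2486 genes were called, 2137 higher and 349 lower (86.0% higher). After quantile normalization 1675 were called, 793 higher and 882 lower (47.3% higher), and 1140 were called in the same direction both ways. Median centring gave 1561, of which 67.3% were higher. The count was 4508 without replicate 1 of Rbp2-/- with LIF, which leaves the dim array, and 1137 and 1073 without replicate 1 and 2 of Rbp2-/- lacking LIF.

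Of the 28 pluripotency factors 25 fell in Rbp2-/-, 2 rose and 1 did not pass, with the same counts adjusted over the list alone and 25 lower with 1 higher after quantile normalization. Their median was -2.70 (adjusted p = 1.3e-46; adjusted p = 0.32 with an estimated correlation). LIF and STAT3 responsive genes gave 7 lower and 2 higher of 20, 8 and 2 adjusted over the list alone, and 9 and 1 after quantile normalization, with Klf4 at -3.20 ± 0.26 and Tfcp2l1 at -3.28 ± 0.29 (median -0.86, adjusted p = 5.0e-08; adjusted p = 0.41 with an estimated correlation). Mesoderm derivatives gave 11 of 17 higher, 12 adjusted over the list alone and 11 after quantile normalization, with Foxf1, a lateral mesoderm factor, at 2.97 ± 0.32 and Msx2 at 2.74 ± 0.33 (median 1.36, adjusted p = 1.2e-05; adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes gave 14 of 16 higher, 15 adjusted over the list alone and 9 after quantile normalization (median 0.87, adjusted p = 1.8e-05; adjusted p = 0.61 with an estimated correlation). Among them Hmgcs1 was at 1.01 ± 0.23 and Cyp51, a sterol demethylase, at 1.70 ± 0.35. Feeder fibroblast markers gave 9 of 17 higher, 10 adjusted over the list alone and 4 after quantile normalization (median 0.77, adjusted p = 0.011; adjusted p = 0.54 with an estimated correlation), with Pdgfrb at 1.89 ± 0.27. Imprinted genes gave 12 of 22 higher, 13 higher and 1 lower adjusted over the list alone and 7 higher after quantile normalization, with Igf2 at 2.50 ± 0.31 (adjusted p = 0.0042; adjusted p = 0.41 with an estimated correlation). Hox genes gave 3 of 7 higher, 4 adjusted over the list alone and 2 after quantile normalization, with Hoxb2 at 2.70 ± 0.41 (adjusted p = 0.020; adjusted p = 0.45 with an estimated correlation).

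Metallothionein and zinc response genes gave 2 of 5 lower in Rbp2-/-, Mt1 at -2.84 ± 0.27 and Mt2 at -2.37 ± 0.26, with 3 lower and 1 higher adjusted over the list alone and 3 lower after quantile normalization (median -1.21, adjusted p = 0.00013; adjusted p = 0.41 with an estimated correlation). Germ cell genes (1 of 5 lower, 2 adjusted over the list alone), E2F target and DNA replication genes (1 lower and 1 higher of 24), Polycomb components (3 lower and 2 higher of 18) and amino acid genes (1 lower and 2 higher of 21) were called lower relative to other genes, with medians of -1.06, -0.44, -0.36 and -0.42. After quantile normalization these gave 3, 7 and 5 lower with 0 higher, and 4 lower with 1 higher. The amino acid list had a median of -0.03 and a mean of 0.06 before the all-gene median was subtracted, and its call was lost after quantile normalization (adjusted p = 0.071). Their adjusted p were 0.00062, 0.0024, 0.0042 and 0.049, and with an estimated correlation adjusted p = 0.45, 0.72, 0.72 and 0.72. Adjusted over the list alone the E2F list gave 1 higher, the Polycomb list 3 lower and 2 higher and the amino acid list 1 higher. Primitive streak genes gave 8 of 12 higher, 3 after quantile normalization, and missed the threshold as a list (median 0.93, adjusted p = 0.082), which quantile normalization passed (0.026). Extraembryonic endoderm (0.33), trophoblast (0.66), interferon-stimulated genes (0.57), p53 targets (0.23), epithelial genes (-0.17), smooth muscle and SRF target genes (-0.20), neuroectoderm (-0.12) and glycolysis genes (0.14) did not pass either. In that order, 7, 7, 8, 4, 3, 2, 0 and 9 members were higher over all genes, and 1, 1, 1, 0, 0, 0, 2 and 0 lower. After quantile normalization 4, 4, 3, 0, 0, 1, 0 and 3 were higher, and 2, 2, 2, 0, 0, 1, 2 and 2 lower. Of the 12 lists called, 8 stayed called whichever array was left out, and the feeder (0.42 to 1.17), Hox (0.25 to 0.64), imprinted (0.69 to 1.09) and amino acid lists (-0.42 to -0.30) did not. Among those that did, E2F targets ranged from -0.59 to -0.25, Polycomb components from -0.515 to -0.21 and metallothionein genes from -1.595 to -0.71.

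**Figure D3:**
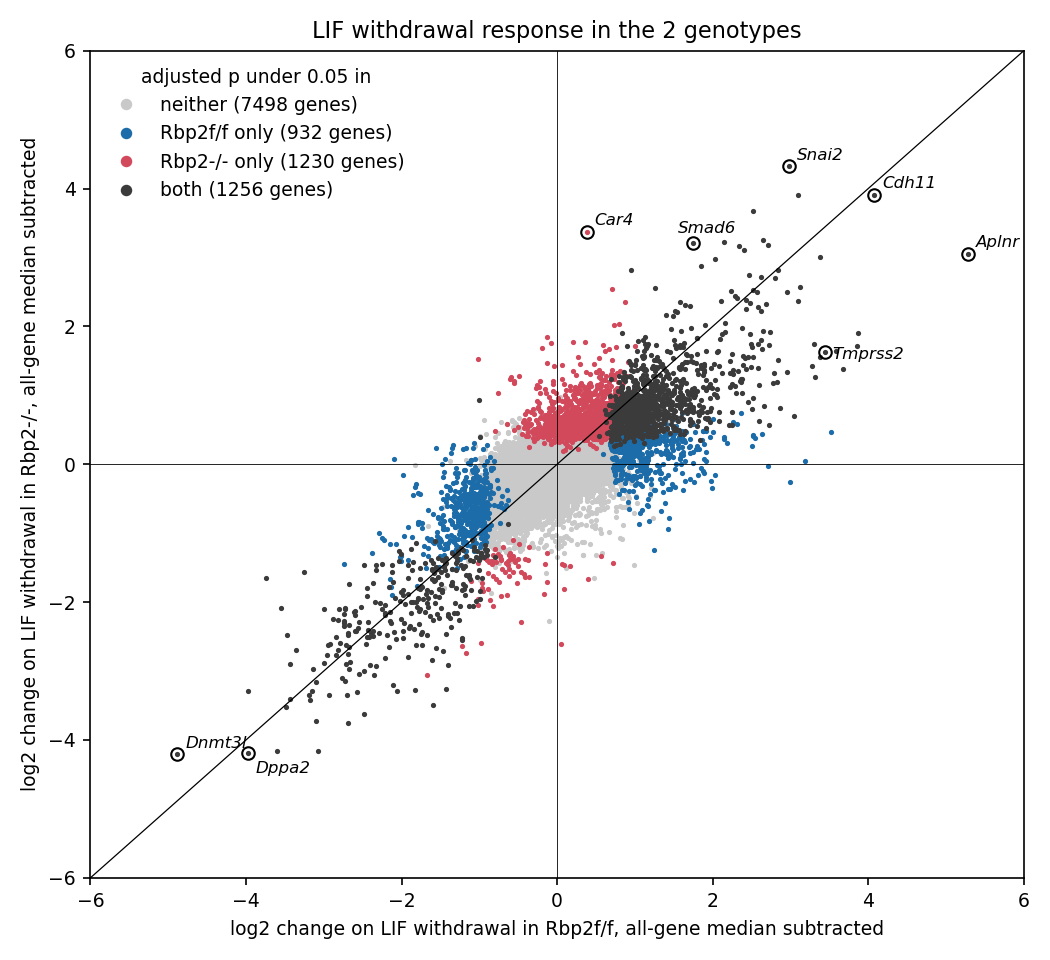
Log2 change on LIF withdrawal of 10916 genes in Rbp2f/f (x axis) and Rbp2-/- (y axis), each minus its all-gene median, with a line of equal change and colours for genes at an adjusted p under 0.05 in both genotypes (1256), in Rbp2f/f (932), in Rbp2-/- (1230) or in neither (7498). The changes correlate at 0.74 across genes, and a difference in colour is not a test of a difference between the genotypes.

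The withdrawal responses of the genotypes, which share no array, correlated at 0.74 across genes (0.74 after quantile normalization). Of the genes called higher, 982 were shared, against 283.1 for independent lists, and of those called lower 272 against 23.7. Only 2 genes were called in opposite directions. After quantile normalization 512 higher and 642 lower genes were shared, against 109.3 and 114.4. Over genes called in Rbp2f/f the change in Rbp2-/- was 0.733 of that in Rbp2f/f, and over genes called in Rbp2-/- the change in Rbp2f/f was 0.754 of that in Rbp2-/-. These values hold the shift from the dim array. They became 0.662 and 0.848 after quantile normalization, and 0.668 and 0.87 after median centring. Picking genes in 1 genotype makes the other look smaller, in both directions. As deposited, the value over genes called in Rbp2-/- was 0.438 without replicate 1 of Rbp2-/- with LIF.

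No gene passed the test of a difference between the withdrawal responses. The smallest p belonged to Magel2, an imprinted gene of the Prader-Willi region, for which the response in Rbp2-/- minus that in Rbp2f/f was 1.95 ± 0.38 relative to the all-gene median of 0.31. Next were the carbonic anhydrase genes Car3 (-2.32 ± 0.37) and Car4 (3.0 ± 0.65), Gbp2 (-3.14 ± 0.55) and the spindlin gene Spin2c (1.88 ± 0.43), all with an adjusted p of 0.21. Limma called 0 genes, with 1268 at an unadjusted p under 0.05, and called 0 with 1220 after quantile normalization. With the replicate number as a block it called 9. Without replicate 1 of Rbp2-/- with LIF the count was 1408, without replicate 2 of Rbp2-/- lacking LIF 7, and without replicate 1 of Rbp2f/f lacking LIF 2. As lists, 18 of 26 passed camera for this signed difference, 6 with a positive and 12 with a negative sign, and 0 passed with an estimated correlation (smallest adjusted p = 0.39). Smooth muscle and SRF target genes (-1.14, adjusted p = 3.3e-11) and epithelial genes (-0.81, adjusted p = 6.5e-06) had the smallest p among the negative lists. After quantile normalization replicate 2 of Rbp2-/- with LIF lay above replicate 1 by a median of 0.89 in the SRF list (17 of 17 members) and of 0.51 in the epithelial list (13 of 17). Without that replicate these lists were at -0.65 and -0.49 (adjusted p = 0.00042 and 0.010), and without replicate 1 of Rbp2-/- lacking LIF at -0.52 and -0.20 (adjusted p = 1.8e-06 and 0.0092). Glycolysis and hypoxia genes (0.54, adjusted p = 8.8e-06) had the smallest p among the positive lists, with 8 of 19 members positive adjusted over the list alone. The thrombospondin gene Thbs1 was at -1.91 ± 0.52, Cldn3 at -1.95 ± 0.50 and Egln3 at 1.85 ± 0.53 in these lists, none past the threshold. After quantile normalization 14 lists passed, and without replicate 2 of Rbp2f/f with LIF 11 did.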

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

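The tests of explanations below, for replicate 2 of Rbp2-/- with LIF and for the remaining Kdm5a signal, were chosen only after the results they bear on were seen, while the tests of the gene lists were planned.

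The test of the difference between the withdrawal responses singled out 18 lists, given here as the median log2 difference (Rbp2-/- minus Rbp2f/f) relative to all genes. The signed difference was negative for smooth muscle and SRF target genes (-1.14), epithelial genes (-0.81), interferon-stimulated genes (-0.81), primitive streak genes (-0.73), trophoblast (-0.70), metallothionein and zinc response (-0.64), LIF and STAT3 responsive genes (-0.50), CDK inhibitors and pocket proteins (-0.48), p53 target genes (-0.47), pluripotency factors (-0.32), extraembryonic endoderm (-0.32) and feeder fibroblast markers (-0.22). It was positive for cholesterol synthesis (0.60), glycolysis and hypoxia genes (0.54), amino acid and ER stress response (0.46), mitosis genes (0.45), E2F target and DNA replication genes (0.30) and oxidative phosphorylation (0.11). A negative sign can mean a smaller rise or a larger fall. Pluripotency, LIF and STAT3 and metallothionein lists fell further in Rbp2-/- (-2.70, -0.86 and -1.21) than in Rbp2f/f (-2.16, -0.24 and -0.56). E2F targets, with a positive sign, fell less (-0.44 against -0.69). After quantile normalization the feeder (-0.14), CDK inhibitor (-0.53), amino acid (0.39) and oxidative phosphorylation (0.04) calls were lost. Without replicate 2 of Rbp2f/f with LIF 7 calls were lost: pluripotency (-0.14), trophoblast (-0.30), feeder (-0.21), CDK inhibitor (-0.41), mitosis (0.32), amino acid (0.17) and cholesterol (0.39). Without replicate 1 of Rbp2-/- with LIF the pluripotency (-0.025) and amino acid (0.28) calls were. Without replicate 1 of Rbp2-/- lacking LIF the streak (-0.43), CDK inhibitor (-0.23), oxidative phosphorylation (0.04) and metallothionein (-0.29) calls were, and the epithelial and SRF lists were at -0.20 and -0.52. Without replicate 2 of that group the feeder (-0.23) and amino acid (0.26) calls were, and without replicate 1 or 2 of Rbp2f/f lacking LIF the amino acid (0.28) or metallothionein call (-0.49). Without replicate 2 of Rbp2-/- with LIF the streak (-0.38), CDK inhibitor (-0.09) and feeder (-0.17) calls were lost, and trophoblast, epithelial genes, p53 targets and SRF targets were at -0.44, -0.49, -0.26 and -0.65. Whichever of the 8 arrays was left out, 8 of the 18 stayed called, namely the SRF, epithelial, interferon, LIF and STAT3, p53, endoderm, E2F and glycolysis lists. With 1 array left out, medians ranged from -1.52 to -0.516 for SRF targets, -1.071 to -0.2 for epithelial and -0.891 to -0.553 for interferon genes. The ranges were -0.823 to -0.298 for LIF and STAT3 genes, -0.747 to -0.263 for p53 targets and -0.554 to -0.251 for endoderm. E2F targets ranged from 0.196 to 0.413 and glycolysis genes from 0.33 to 0.75. With an estimated correlation or with fry, 0 of the 18 lists passed, with a smallest adjusted p of 0.39 for the former, and single genes passing in limma numbered 0 with 1268 at an unadjusted p under 0.05.

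Probe sets named after no single gene, which the comparisons of genes leave out, also changed on withdrawal. Of 1753 tested, limma called 195 in Rbp2f/f (114 higher, 81 lower) and 236 in Rbp2-/- (205 higher, 31 lower). After quantile normalization, added for these probe sets after the counts were seen, 1747 were tested, and limma called 259 (113 higher, 146 lower) and 119 (52 higher, 67 lower).

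Replicate 2 of Rbp2-/- with LIF lay towards the arrays without LIF: over 2921 genes, its difference from replicate 1 had a slope of 0.22 on the withdrawal change in Rbp2f/f after quantile normalization, against 0.04 for the Rbp2-/- pair without LIF on the same change, and 0.09 and -0.06 for the Rbp2f/f pairs with and without LIF on the change in Rbp2-/- over 1675 genes. The slope was 0.25 as deposited. The median difference was subtracted before each fit. The log2 scale used understates the change of dim genes, so dimming by a common factor leaves differences that this subtraction does not remove. Such dimming may have given part or all of the slope of 0.25 as deposited. Quantile normalization keeps only the rank of each gene within an array, so such dimming could not have given the slope of 0.22. Brightness effects that differ between genes were not tested beyond quantile normalization. Feeder fibroblasts in the culture and some cells changed as without LIF cannot be told apart: feeder markers differed by 0.05 (12 of 17 higher), primitive streak genes by 0.54, mesoderm derivatives by 0.20 and pluripotency factors by -0.26. A rise of feeder markers, which feeder cells would give, was not seen beyond 0.05. In that list the other replicate pairs stood at -0.36, -0.15 and -0.44. With that spread a small rise could be missed, so feeder cells were not excluded. What keeps some cells changed as without LIF open is that other pairs differed about as much or more. They differed by 1.61 in the streak list, -0.54 in the mesoderm list and -0.22 in the pluripotency list. Other shifts in this pair were in smooth muscle and SRF target genes (0.89), p53 targets (0.58), imprinted genes (0.51) and epithelial genes (0.51), and no explanation was tested for these.

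Kdm5a signal in Rbp2-/- cells without LIF was 38.2% of that in Rbp2f/f. Rbp2f/f cells in the Rbp2-/- cultures, as its whole source, would leave at least that share of every transcript, and of 5105 genes with a mean of 200 or more in Rbp2f/f, 2 lay below that share on every array. These were Grb10 at 7.7% (17.0% for its higher Rbp2-/- array over its lower Rbp2f/f array) and Cd248, named after its value was seen, at 31.0% (37.8%). Grb10 goes against such cells as the whole source, but these are 2 genes where the bound was 5 or more, and an earlier, looser bound, changed after the value was seen, would have counted them in favour of such cells. This explanation cannot be told apart from probe sets that lie outside the deleted part, for which the brighter 3 left a median of 42.3% (38.2% to 51.1%), and what keeps it open is that the place of the probes relative to the deletion was not analysed here.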

How the results depend on the processing

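Over 78 list results and 62 single-gene results, 1693 of 2006 and 1283 of 1519 alternative values kept direction and side of the threshold; 308 and 232 lost the call, 4 values, all of Kdm5a on withdrawal in Rbp2f/f, gained one and 5 list values reversed. Direction here is that of the test; where the call was lost, the median also changed sign for SRF targets with LIF without replicate 2 of Rbp2-/- with LIF (-0.103, and -0.11 with quantile normalization as well), trophoblast with LIF (-0.007) and neuroectoderm without LIF (0.036) with no filter, and LIF and STAT3 genes in Rbp2f/f with a filter at the 60th percentile (0.044). Quantile normalization with 1 array left out was chosen after seeing the data, in 3 versions. Where 1 array was left to a group, it was assumed to vary like the other groups. Dim genes near background limit the folds, and the causes were not tested except where the alternative itself tests other genes or fewer arrays.

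Genes called with LIF (25) and without LIF (3) became 0 and 0 with quantile normalization, median centring, no filter or adjusted p under 0.01, 0 and 479 with array weights, 3 and 0 with the mean of probe sets, and 11 and 0 with every probe set. With only the 4 arrays of the comparison the count with LIF was 72. Without LIF it was 8 with a filter at the 60th percentile, 55 with pseudocount 64 and 5 with robust eBayes. Withdrawal in Rbp2f/f (2188) gave 1040 at adjusted p under 0.01, 3664 with array weights and 3329 with 4 arrays. Withdrawal in Rbp2-/- (2486) gave 1059, 1001 with array weights, 1561 with median centring and 1589 at 2-fold or more. Quantile normalization without replicate 2 of Rbp2-/- with LIF gave 0 and 1 for genotype, 3298 and 1622 for withdrawal, and 3 lists with LIF, all lower. Without replicate 1 of Rbp2f/f with LIF it gave 2 and 0 for genotype, and without replicate 1 of Rbp2-/- lacking LIF 0, 0 and, for withdrawal in Rbp2-/-, 549.

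Kdm5a with LIF missed the threshold with array weights (-1.79, adjusted p = 0.33), no filter (-1.79, 0.16), mean of probe sets (-0.86, 0.16), median centring (-1.66, 0.054) and quantile normalization (-1.60, 0.078; -1.75 without replicate 2 of Rbp2-/- or replicate 1 of Rbp2f/f with LIF, 0.17 and 0.14; -1.60 without replicate 1 of Rbp2-/- lacking LIF, 0.092). Without LIF Kdm5a passed with array weights (-1.25, 0.0077) and pseudocount 64 (-0.96, 0.038).

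With an estimated correlation camera called 0 lists in each of the 5 contrasts. That test also missed pluripotency factors on withdrawal, of which 25 of 28 fell in each genotype (adjusted p = 0.34 in Rbp2f/f and 0.32 in Rbp2-/-). Missing it is therefore weak evidence against a list. Fry called 10 for withdrawal in Rbp2f/f, 8 in Rbp2-/- (7 higher, 1 lower) and 0 for genotype with LIF, genotype without LIF and the interaction. Fry tests values against no change and not against other genes, and gave the other direction, far from the threshold, for endoderm with LIF (adjusted p = 0.97) and amino acid genes on withdrawal in Rbp2-/- (adjusted p = 0.72), whose medians relative to all genes stayed 0.287 and -0.415. Primitive streak genes without LIF ranged from -1.173 to 0.443 with an array left out, the latter without replicate 1 of Rbp2-/- lacking LIF, and turned to 0.435 with quantile normalization as well, which also turned oxidative phosphorylation in the interaction to -0.023.

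Replicates 2 minus 1 correlated at 0.26 in 3 of 6 pairs of groups and at -0.08, -0.05 and 0 in the others, which hold Rbp2f/f with LIF, so the numbers were not treated as pairing. Such correlations across all genes do not exclude pairing of cultures or clones. In Rbp2f/f, Rian read 163.3 and 258.3 in replicate 1 with and without LIF, and 9.4 and 17.6 in replicate 2. Meg3 also followed the number in both media. Both genes were picked out after their values were seen. With the number as a replicate block, 140 genes were called with LIF, 149 without and 9 for the interaction, and Kdm5a without LIF passed (-1.25, adjusted p = 0.020).

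Leaving out each array in turn gave 0 to 2425 genes and 3 to 11 lists with LIF, 0 to 125 and 17 to 20 without, 856 to 3304 and 17 to 22 for withdrawal in Rbp2f/f, 1073 to 4508 and 12 to 17 in Rbp2-/-, and 0 to 1408 and 11 to 20 for the interaction. Kdm5a ranged from -1.97 to -1.62 with LIF and from -1.39 to -1.12 without, and the slopes between withdrawal responses from 0.611 to 0.793 and from 0.438 to 0.801.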

Other observations

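The tests of the Y-linked and imprinted genes were chosen only after their values were seen.

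Some Y-linked and imprinted genes differed between the genotypes in the same direction in both media. Eif2s3y read 204.9 and 64.8 in Rbp2-/- with LIF and 190.6 and 118.8 without, against 9.3, 4.1, 14.0 and 3.9 in the Rbp2f/f arrays, and Uty, another Y-linked gene, read 66.4, 46.9, 107.3 and 95.7 against 22.9, 2.4, 40.6 and 6.8. The dimmer Y-linked genes Zfy2, Uba1y and Usp9y had 1, 1 and 2 of the 4 Rbp2-/- arrays above every Rbp2f/f array, and Kdm5d had 3. Xist, the RNA that coats an inactive X chromosome, stayed between 21.0 and 49.2 on all 8 arrays. Among the imprinted genes, Peg10 and Sgce, which are neighbours, were both higher in Rbp2-/- (Peg10 at 502.1 and 535.7 against 56.9 and 255.5 with LIF, and 1515.8 and 1342.3 against 467.6 and 476.1 without), while Grb10 was lower, and only Sgce and Grb10 of 22 passed in limma over all genes. The estimates for Magel2 (-0.89 with LIF, 1.37 without), Phlda2 (-1.49, 0.40) and Dlk1 (0.23, -0.92) had opposite signs in the media. No gene passed the interaction test, so a change of direction was not shown for them. The non-coding RNAs Meg3, Rian and Mirg of one imprinted region split the Rbp2f/f replicates, with Rian at 163.3 and 258.3 in replicate 1 and 9.4 and 17.6 in replicate 2, and Meg3 at 295.6 and 467.5 against 65.5 and 45.1. In Rbp2-/- Rian read 247.9, 374.9, 490.0 and 400.6. Cdkn1c read 19.1 and 925.3 in the replicates of Rbp2-/- without LIF. Xist, Meg3, Rian, Mirg and the dimmer Y-linked genes were picked out after their values were seen, as was the contrast between media in Magel2, Phlda2 and Dlk1.

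The dim array or its scaling was argued against as the whole origin of the differences seen with LIF. Of 24 Y-linked and imprinted genes, 11 passed with LIF when adjusted over these genes alone. In the comparison without that array, after quantile normalization, their median log2 difference was 1.57 in the direction seen with LIF (lower bound from resampling the genes, 0.29), with 9 of 11 in that direction and Magel2 and Phlda2 the other way. That bound treats the genes as independent, though Peg10 and Sgce are neighbours and Eif2s3y and Uty are both Y-linked. It measures the spread between genes and not between cultures. A separate history of the cell lines, before or apart from the deletion, is a hypothesis that cannot be told apart from an effect of losing RBP2. Relative to all genes, 19 of 22 imprinted genes differed in the same direction in both media, which either would give, and the labels do not say how many clones each genotype stands for.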
